A study of Mus musculus with 6 samples.

How the data were processed

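RNA from inguinal fat of 6 samples of male C57BL/6J mice, 3 titled DIO and 3 titled DIO_CR_WR, was measured on 6 Agilent 1-colour arrays of design 028005, with 1 array per sample. Per the labels, Cy3 cRNA was made from 0.5 µg of RNA. The deposited values are spot intensities: per the file headers, the submitters' Feature Extraction software subtracted a local background with a spatial trend, corrected a trend in brightness within each array, and set signals near the background to a surrogate value. It did not normalize between arrays. The submitters' processing notes give version 10.7.1.1 of that software and the file headers give 10.7.3.1. The files also hold the unprocessed intensity of each spot with its local background, as deposited, and flags of 0 or 1 per spot for signal well above background, saturation and outliers. A table of the whole series, with 18 columns of values per sample, was not used here, because its column names do not match the sample titles and the same measurements are in the files of the single arrays.

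Groups follow the sample titles. The protocol and design text use DIO for the mice that regained weight and CTR for the others, while the titles use DIO_CR_WR and DIO, and the files under the title DIO carry CTR in their names. No label states a pairing, and replicate numbers were not treated as pairs. To check this, each array's deviations from its group mean were correlated across genes between the groups, which gave −0.01, −0.12 and −0.24 for arrays of the same number and −0.11 to 0.24 for other numbers. Genes are not independent replicates. The slide of each array was taken from the array files.

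All computation used R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table. The 3671 control spots were set aside, spots with an outlier flag were treated as missing, and spots of the same probe were averaged on the log2 scale, which left 55681 probes. Each array was scaled by subtracting the 75th percentile of its log2 processed intensity over all non-control probes. A probe was kept if it was well above background on at least 3 of the 6 arrays, which held for 38791, and 334 of these were left out for an outlier flag on some array. For each gene name the probe with the highest mean over all 6 arrays was taken, giving 26177 genes. Of these 16011 had an accession that matched a current symbol in the reference table of mouse genes, 1727 got an updated symbol, and 3755 are named only by a chromosome range. Probe positions are those in the array files, on build mm9, and no position from the reference table was used. Precision was limited by the number of arrays and by signal over background. The standard deviation of the negative control spots was 5.12 to 5.74 on the DIO arrays and 6.58 to 21.7 on the DIO_CR_WR arrays. Where a gene was well above background on no array of a group, its fold is given as a bound, with each array of that group at no less than its own lowest signal called well above background.

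DIO_CR_WR was compared with DIO by limma's two-sided moderated test with Benjamini-Hochberg adjustment over all genes at 0.05. Gene lists for pathways and cell types, 35 in all, were fixed before the data were examined, together with the model, the rule for named genes and the main alternatives. Lists with at least 5 measured members were tested by camera with a preset correlation of 0.01, two-sided and adjusted over the lists. The lists were also tested by camera with an estimated correlation and by fry. A list's score on an array is the mean deviation of its members from their means over the 6 arrays, minus that of all genes tested. Gene families that share a symbol stem, with at least 10 measured members, were tested in the same way after the lists. List medians were compared with 10000 random lists matched on brightness in 50 bins.

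The genes named are the 12 higher and 12 lower genes with the largest change among those past the threshold with no overlap between groups. Since no gene passed, the 12 with the smallest unadjusted p in each direction were taken. From each list up to 4 members past the threshold, otherwise the 2 with the smallest p, were named, and Lep, Adipoq, Cd4, Ucp1 and Pparg were always named. Clone names, Gm numbers, accessions and chromosome ranges were not eligible. Results of 3 genes that these rules picked are left out of the text and the plot of single genes, and these genes stay in all tests and counts.

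Alternatives planned before the data were examined were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, centring on the median, no filter on dim probes, a filter for signal on all 6 arrays, every probe or the mean of a gene's probes, a trended and robust variance, replicate number or slide as a block, age as a covariate, an adjusted p under 0.1, a change of at least 2-fold, and leaving out each array. Added after seeing the data were slide 1 alone, scaling to the 8 of 10 E1A spike-in probes well above background on all arrays, 1 common floor for all arrays, and the count at an unadjusted p under 0.05. The processing was tested on simulated data for the comparison of DIO_CR_WR with DIO, with 26177 genes of which 200 were changed. It recovered 7% of genes changed 2-fold and 73% of genes changed 4-fold, with 12 false calls. A list shifted by 0.5 had an adjusted p of 6.95e-05 in camera. In 50 simulations with 35 unchanged lists whose genes had a correlation of 0.25, camera with the preset correlation called a mean of 7.24 lists and camera with an estimated correlation called 0. The setting with an estimated correlation was not simulated with changed lists, so its power is not known.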

Results

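Gene expression was measured in inguinal fat, a fat depot under the skin, of male C57BL/6J mice with 1-colour Agilent microarrays, 3 arrays in each of 2 groups. In the group titled DIO_CR_WR, mice aged 2 months ate a diet with 60% of its energy from fat for 1 month. They were then held on fewer calories for about 3 weeks, until they weighed as much as mice of the same age on chow, and afterwards ate the fatty diet freely and regained weight. The mice of the other group, titled DIO, ate chow up to that point and then the fatty diet over the same last period. The protocol calls the DIO_CR_WR mice DIO and the other mice controls, and the groups here follow the sample titles. The age labels run from 6 to 11 months, differ for every sample, and do not overlap between the groups. They rise by 1 month from each sample to the next in the order of the samples, so they may not be true ages, and a model with age as a covariate may follow that order. The labels do not state whether each sample came from a single mouse.

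Each array carried 62976 spots. The 75th percentile of the signal was 4991, 4724 and 4605 on DIO arrays 1 to 3 and 7126, 6858 and 6050 on DIO_CR_WR arrays 1 to 3. Between 68.2% and 79.2% of the non-control probes were well above background on the DIO arrays, and between 51.6% and 65.7% on the DIO_CR_WR arrays. No spot was saturated (0 on each array). DIO replicate 1 and the 3 DIO_CR_WR arrays were on slide 1, and DIO replicates 2 and 3 were on slide 2. The number of arrays limits the precision of every value. On the first principal component, which held 44.6% of the variance, DIO replicate 1 lay at −16.6, between the other DIO arrays at −69.2 and −57.5 and the DIO_CR_WR arrays at 19.7 to 76.4.

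The comparison asks how inguinal fat with a history of obesity, weight loss and regain differs from fat of mice that met the fatty diet without that history. In a test of gene lists at a preset correlation between genes, lists of cytokines and chemokines, the secreted signals that recruit immune cells, of natural killer (NK) cells and of T cells were higher in DIO_CR_WR fat, and lists of oxidative phosphorylation, skeletal muscle and the circadian clock were lower. With a correlation estimated from the arrays 0 of these lists passed, and 0 single genes passed over all genes. The oxidative phosphorylation call was also lost with quantile normalization, and the muscle and clock calls with the labelled age as a covariate. Relative to all genes, the mean score of the cytokine and chemokine list was 0.59 ± 0.19 in DIO_CR_WR and −0.59 ± 0.25 in DIO (log2, SD, n = 3 arrays each). The score of the oxidative phosphorylation list was −0.15 ± 0.08 in DIO_CR_WR and 0.15 ± 0.02 in DIO (log2, SD, n = 3 arrays each). Fold changes below are DIO_CR_WR relative to DIO with the standard error (SE) of limma's model and 3 arrays per group. A list's shift is the median log2 fold change of its measured members minus that of all genes, which was −0.20.

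Of 35 gene lists, 15 rose and 5 fell at an adjusted p under 0.05 in limma's camera, which compares a list with all other genes at a preset correlation of 0.01. For 16 of these 20 lists the scores of the groups' arrays did not overlap. With a correlation estimated from the arrays, camera called 0 of the 35 lists, and that estimate gave the highest adjusted p of all alternatives for 13 of the 20. Immediate early, clock and lymph node stroma genes lost their calls there although their estimated correlations, −0.04, −0.04 and −0.08, lay below the preset 0.01. The loss of a call in that setting thus does not show that correlation among members explains the call. The rotation test fry, which asks whether a list's own members move one way, passed 11 lists, 4 higher and 7 lower. Fry kept 9 of the 20. It does not compare with other genes, whose median log2 fold change was −0.20, so a list that follows all genes can pass as lower. With the slide as a block in the model, camera passed 23 lists, of which 18 were shared with the 20 and had the same direction. The other 5 were the dendritic cell, MHC class II, cholesterol, fatty acid oxidation and interferon lists. Because slide 2 holds DIO arrays alone, the blocked fold changes rest on DIO replicate 1 as the only DIO array beside the 3 DIO_CR_WR arrays. Without the filter on dim probes 12 lists passed, and with the labelled age as a covariate 9 passed.

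No single gene passed: limma called 0 of 26177 genes, with a smallest adjusted p of 0.108. At an unadjusted p under 0.05 it gave 7080 genes, 1420 higher and 5660 lower in DIO_CR_WR, where 1309 were expected by chance. With arrays scaled to spike-ins 4961 were higher and 907 lower, so which direction holds most genes depends on the scaling. The groups' arrays did not overlap for 8838 genes (33.8%), where chance gives 10%. The counts were 0 and 2761 with the slide as a block, and 0 and 2759 on slide 1 alone. Limma with a trended, robust variance called 26 genes, the filter for signal on all arrays 63, and leaving out DIO replicate 1 called 4057. Without DIO replicate 1 the groups were on different slides, so those calls cannot be told apart from a slide difference. Leaving out DIO replicate 2, DIO_CR_WR replicate 1 or DIO_CR_WR replicate 2 lowered the count at an unadjusted p under 0.05 to 3204, 4528 and 4534.

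**Figure D1:**
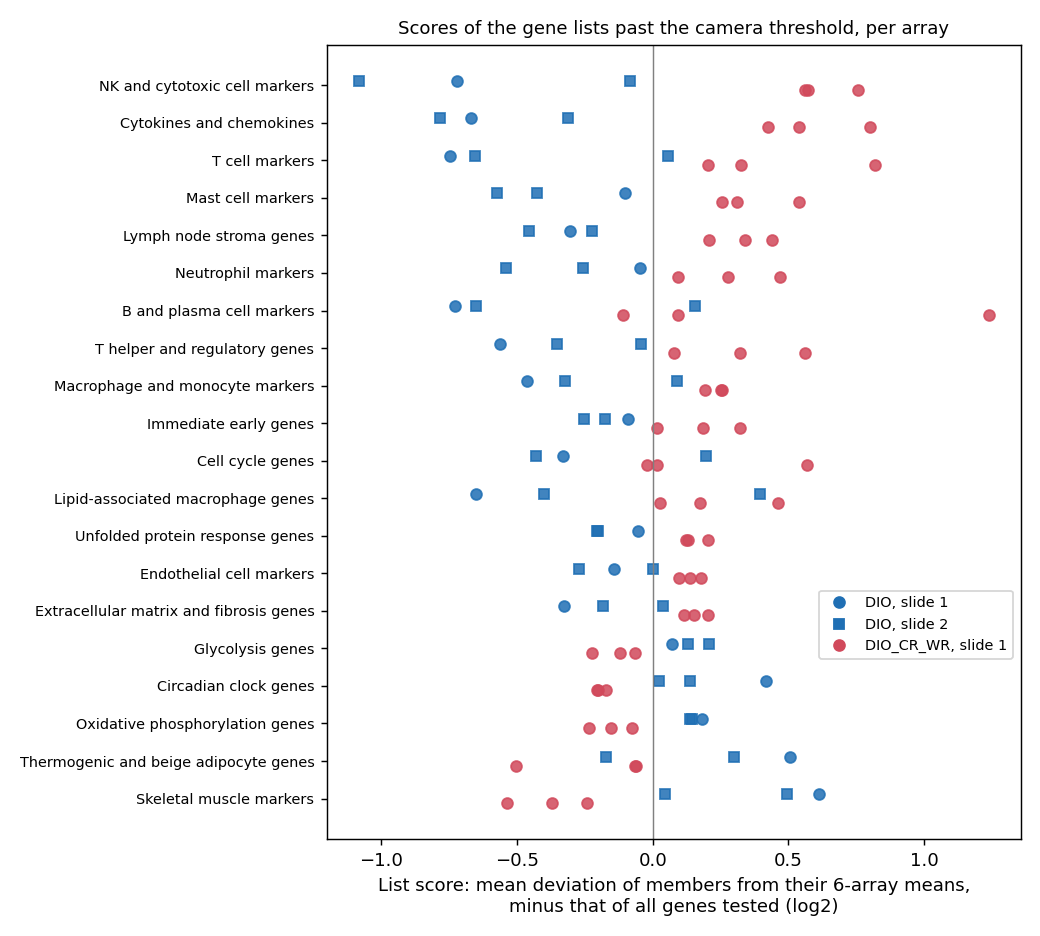
Score of each of the 20 gene lists past the camera threshold on each array (x axis, log2, mean deviation of the members minus that of all genes); blue marks are DIO arrays (circles slide 1, squares slide 2) and red circles are DIO_CR_WR arrays. For cytokines and chemokines the DIO_CR_WR arrays sit between 0.42 and 0.80 and the DIO arrays between −0.78 and −0.31.

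Cytokines and chemokines gave the lowest camera p of the lists. Their list of 28 measured genes rose by a shift of 1.12 (camera adjusted p = 4.25e-14, and adjusted p = 0.213 with an estimated correlation) and by 1.19 with the slide as a block. Of its members 16 were higher and 0 lower at an unadjusted p under 0.05. None passed over all genes tested (0), and 12 passed adjusted over the list alone. Cxcl5, a chemokine for neutrophils, was 7.37-fold higher (log2 2.88 ± 0.42 SE), with signal well above background on 2 of 3 arrays of each group. Saa3, an acute-phase protein made by fat and macrophages, was 3.32-fold higher (log2 1.73 ± 0.34 SE). Among members chosen after their values were seen, the monocyte chemokine Ccl7 had a log2 fold change of 1.42 ± 0.31 SE, the interferon-induced T cell chemokine Cxcl10 1.85 ± 0.44 SE, and interleukin 1 beta (Il1b) 1.02 ± 0.26 SE.

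Lymphocyte lists rose together. The NK and cytotoxic cell list rose by a shift of 1.30 (camera adjusted p = 8.2e-09, and adjusted p = 0.302 with an estimated correlation) and by 1.54 with the slide as a block. Of its 13 measured genes 8 were higher and 0 lower at an unadjusted p under 0.05, with 0 past the test over all genes and 7 adjusted over the list alone. The NK cell receptor genes Klre1 and Klrk1 had log2 fold changes of 1.1 ± 0.19 and 2.24 ± 0.41 SE. Klrk1 was well above background on 1 DIO array and 2 DIO_CR_WR arrays. T cell markers rose by 1.06 (camera adjusted p = 1.02e-06, and adjusted p = 0.392 with an estimated correlation), and by 1.39 with the slide as a block. Of 21 measured T cell markers 11 were higher and 1 lower at an unadjusted p under 0.05, with 0 past the test over all genes and 0 adjusted over the list alone. Cd3g, a chain of the T cell receptor complex, was 3.04-fold higher (log2 1.61 ± 0.38 SE), and Cd28, which gives T cells their second activation signal, had a log2 fold change of −0.94 ± 0.25 SE (−0.57 with the slide as a block). Cd4, the co-receptor of helper T cells, had a log2 fold change of −0.10 ± 0.27 SE, which was 0.38 with the slide as a block and 0.37 when arrays were scaled to spike-ins. The T cell list did not pass in fry.

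T helper and regulatory genes rose by a shift of 0.58 (18 measured, camera adjusted p = 1.39e-03, and adjusted p = 0.392 with an estimated correlation), by 0.89 with the slide as a block and by 1.03 without DIO_CR_WR replicate 2. The call was lost without the filter on dim probes (shift 0.35), with age as a covariate (0.45) and in fry. Of the T helper genes 4 were higher and 3 lower at an unadjusted p under 0.05, with 0 over all genes and 4 higher and 1 lower adjusted over the list alone. Interferon gamma (Ifng) was 3.82-fold higher (log2 1.93 ± 0.29 SE). The 3 lower members, chosen after their values were seen, were Il12rb2, a receptor chain for interleukin 12, Tbx21, the regulator of type 1 helper cells, and Foxp3, the regulator of regulatory T cells. Their log2 fold changes were −0.92 ± 0.23, −0.95 ± 0.38 and −0.82 ± 0.34 SE, and −1.06, −0.06 and −0.05 with the slide as a block.

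B and plasma cell markers rose by 0.62 (16 measured, camera adjusted p = 7.58e-03, and adjusted p = 0.421 with an estimated correlation) and by 0.92 with the slide as a block. Of these, 3 were higher and 1 lower at an unadjusted p under 0.05, with 0 past the test over all genes and 0 adjusted over the list alone. Fcrla, an Fc receptor-like protein of B cells, was 3.09-fold higher (log2 1.63 ± 0.41 SE), while complement receptor 2 (Cr2) had a log2 fold change of −0.83 ± 0.21 SE, in which 1 of its 2 probes went the other way. The call was lost without DIO replicate 1 (shift 0.55) and without DIO_CR_WR replicate 1 (0.28), and the shift was 0.95 without DIO_CR_WR replicate 3. It was also lost without the filter on dim probes (0.53), with spike-in scaling and in fry. Beside the lymphocyte lists, stroma genes of lymph nodes, which lie within the inguinal depot, rose by 0.76 (8 measured, camera adjusted p = 5.41e-03, and adjusted p = 0.302 with an estimated correlation) and by 0.63 with the slide as a block. Of the stroma genes 3 were higher and 1 lower at an unadjusted p under 0.05, 0 over all genes, and the same numbers, 3 and 1, adjusted over the list alone. The T zone chemokine Ccl19 was 1.82-fold higher (log2 0.86 ± 0.15 SE), and Chst4, a sulfotransferase of high endothelial venules, had a log2 fold change of −1.04 ± 0.18 SE. The stroma call was lost with age as a covariate (shift 0.90) and with spike-in scaling.

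Among myeloid cells, macrophage and monocyte markers rose by a shift of 0.50 (18 measured, camera adjusted p = 2.04e-04, and adjusted p = 0.421 with an estimated correlation) and by 0.72 with the slide as a block. At an unadjusted p under 0.05, 2 members were higher and 0 lower, with 0 over all genes and 2 adjusted over the list alone. These were the scavenger receptor Msr1, 2.40-fold higher (log2 1.27 ± 0.23 SE), and the mannose receptor Mrc1, 1.60-fold higher (log2 0.67 ± 0.15 SE). The macrophage call was lost with age as a covariate (shift 0.19) and in fry. Genes of lipid-associated macrophages, which take up lipid in obese fat, rose by 0.32 (15 measured, camera adjusted p = 0.032, and adjusted p = 0.637 with an estimated correlation), and by 0.90 with the slide as a block. Of these 2 were higher and 1 lower at an unadjusted p under 0.05, with 0 over all genes and 1 adjusted over the list alone. Osteopontin (Spp1) was 2.97-fold higher (log2 1.57 ± 0.16 SE) and the integrin Itgax 2.20-fold (log2 1.14 ± 0.33 SE, and 0.12 with age as a covariate). The list's call was lost without DIO replicate 1 (shift 0.05) and without DIO_CR_WR replicate 2 (0.19). Its shift was 0.66 without DIO replicate 3. The call was also lost with age as a covariate (−0.25), without the filter on dim probes (0.22), with the filter for signal on all arrays (0.25) and in fry.

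Mast cell markers rose by 0.84 (7 measured, camera adjusted p = 1.69e-03, and adjusted p = 0.302 with an estimated correlation), by 0.33 with the slide as a block and by 0.55 without DIO replicate 3. Here 2 were higher and 0 lower at an unadjusted p under 0.05, with 0 over all genes and 1 adjusted over the list alone. Fcer1a, the binding chain of the IgE receptor, was 2.99-fold higher (log2 1.58 ± 0.22 SE) and the mast cell protease Cpa3 1.63-fold (log2 0.70 ± 0.26 SE, and 0.22 with the slide as a block). Neutrophil markers rose by 0.69 (12 measured, camera adjusted p = 5.41e-03, and adjusted p = 0.302 with an estimated correlation), but not with the slide as a block, where the shift was 0.36. This call was also lost without the filter on dim probes (shift 0.59), with spike-in scaling and in fry. Of the neutrophil genes 2 were higher and 1 lower at an unadjusted p under 0.05, with 0 over all genes and 0 adjusted over the list alone. The alarmin S100a8 had a log2 fold change of 1.02 ± 0.33 SE and the receptor Csf3r −0.57 ± 0.20 SE, which were 0.30 and −0.25 with the slide as a block. Dendritic cell markers did not pass (10 measured, shift 0.32, camera adjusted p = 0.0501; 3 higher and 1 lower at an unadjusted p under 0.05, 0 over all genes and 1 adjusted over the list alone), and had a shift of 0.62 and passed with the slide as a block. It also passed with probe means, the replicate block and spike-in scaling. Without each array the dendritic cell shift ran from 0.22 to 0.45, and it passed without DIO replicate 2, DIO replicate 3 or DIO_CR_WR replicate 3. Cd209a and Siglech, markers of monocyte-derived and plasmacytoid dendritic cells, had log2 fold changes of 0.72 ± 0.16 and −0.52 ± 0.16 SE.

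Genes of antigen presentation on MHC class II did not pass (10 measured, shift 0.33, camera adjusted p = 0.177), with 0 members at an unadjusted p under 0.05. Their regulator Ciita had a log2 fold change of −0.50 ± 0.25 SE and H2-Oa 0.75 ± 0.39 SE, which were −0.28 and 1.38 with the slide as a block. Leaving out DIO replicate 2 gave −0.25 for Ciita, and leaving out DIO replicate 1 gave 0.43 for H2-Oa. The class II list passed with the slide as a block (shift 0.48, adjusted p = 0.00445, range over the alternatives 0.00445 to 0.906), with quantile normalization (0.31) and with normexp added (0.29). Its shift ran from 0.17 to 0.44 without each array, and it passed without DIO replicate 3. Interferon-stimulated genes did not pass either (22 measured, shift 0.05, camera adjusted p = 0.667), with 0 members at an unadjusted p under 0.05. Gbp2, a GTPase induced by interferon, had a log2 fold change of 0.42 ± 0.20 SE (0.15 with the slide as a block, 0.23 without DIO replicate 2), and the RNA sensor Ifih1 −0.33 ± 0.18 SE (0.13 when arrays were scaled to spike-ins). The list's score was 0.75 on DIO replicate 1 and at or below −0.17 on the other DIO arrays. With the slide as a block it fell by 0.70, past the camera threshold, and it was also called lower without DIO replicate 2 (shift −0.24). It was called higher without DIO replicate 1 (shift 0.44) and with age as a covariate (0.91).

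Oxidative phosphorylation genes, which encode the mitochondrial respiratory chain, fell by 0.34 as a list of 29 (camera adjusted p = 1.28e-04, and adjusted p = 0.392 with an estimated correlation), and had a shift of −0.31 with the slide as a block. Its members were lower in 18 cases and higher in 0 at an unadjusted p under 0.05. Over all genes 0 passed, and 14 were lower adjusted over the list alone. The complex III subunit Uqcrc1 had a log2 fold change of −0.75 ± 0.16 SE and the complex I subunit Ndufb5 −0.71 ± 0.16 SE, with 2 of 3 Ndufb5 probes in that direction. The call was lost with quantile normalization (shift −0.12) and with normexp background and quantile normalization (shift −0.08). Beside this list, skeletal muscle markers fell by 0.46 (16 measured, camera adjusted p = 1.76e-03, and adjusted p = 0.39 with an estimated correlation), and had a shift of −0.58 with the slide as a block. Of the muscle genes 9 were lower and 0 higher at an unadjusted p under 0.05, 0 over all genes and 8 lower adjusted over the list alone. The calcium store protein Casq1 and the calcium pump Atp2a1 of muscle had log2 fold changes of −1.14 ± 0.20 and −1.06 ± 0.19 SE. The fast myosin Myh2, chosen after its values were seen, had a log2 fold change of −4.71 ± 1.36 SE. The muscle call was lost with age as a covariate (shift −0.42, adjusted p = 0.633, the largest of its alternatives).

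Thermogenic and beige adipocyte genes fell by 0.42 (22 measured, camera adjusted p = 0.0176, and adjusted p = 0.408 with an estimated correlation), and had a shift of −0.57 with the slide as a block. At an unadjusted p under 0.05, 7 were lower and 0 higher, with 0 over all genes and 5 lower adjusted over the list alone. Ppara, the receptor that drives fatty acid oxidation, and Ppargc1a, the coactivator of mitochondrial biogenesis, had log2 fold changes of −1.17 ± 0.22 and −0.96 ± 0.18 SE. Ucp1, the uncoupling protein of heat-making adipocytes, varied within groups and had a log2 fold change of −0.40 ± 0.72 SE, which was −0.98 with the slide as a block and 0.06 when arrays were scaled to spike-ins. The list's call was lost without DIO replicate 1 (shift −0.30) and without DIO_CR_WR replicate 3 (−0.31), and with age as a covariate, where the shift was 0.22. Several of its members, Ppara, Ppargc1a, Fabp3, Cox8b and Cpt1b, are also expressed in muscle, whose markers moved the same way; the last 3 were chosen after their values were seen. Glycolysis genes fell by 0.29 (19 measured, camera adjusted p = 0.0194, and adjusted p = 0.421 with an estimated correlation), with 11 lower and 0 higher at an unadjusted p under 0.05, 0 over all genes and 4 lower adjusted over the list alone. The phosphofructokinase Pfkm and hexokinase 2 (Hk2), both of muscle and fat, had log2 fold changes of −0.78 ± 0.18 and −0.65 ± 0.15 SE. The glycolysis call was lost with the slide as a block (shift −0.29), without DIO_CR_WR replicate 1 (−0.25), with age as a covariate (−0.37), with spike-in scaling, and with quantile normalization (−0.07), also after normexp background (−0.13). Fatty acid oxidation genes did not pass (23 measured, shift −0.14, camera adjusted p = 0.0638), with 7 lower and 0 higher at an unadjusted p under 0.05, 0 over all genes and 2 lower adjusted over the list alone. Blocked by slide, the list passed with a shift of −0.20, and without each array its shift ran from −0.22 to −0.09. It also passed without the filter on dim probes (−0.23), with the filter for signal on all arrays (−0.20), in fry, and without DIO replicate 2, DIO replicate 3 or DIO_CR_WR replicate 2. Acadvl, which starts the oxidation of long fatty acids, had a log2 fold change of −0.72 ± 0.17 SE.

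Genes of the adipocytes themselves did not pass as a list (21 measured, shift −0.16, camera adjusted p = 0.283). Of these 5 were lower and 0 higher at an unadjusted p under 0.05, with 0 over all genes and 3 lower adjusted over the list alone. The shift ran from −0.22 to −0.02 without each array. The fatty acid transporter Cd36 and adipsin (Cfd) had log2 fold changes of −0.66 ± 0.14 and −0.83 ± 0.20 SE (−0.54 for Cfd with the slide as a block), and the list passed in fry. Leptin (Lep), the satiety hormone of fat, had a log2 fold change of −0.01 ± 0.15 SE, which was 0.08 with the slide as a block, 0.27 with quantile normalization and 0.45 when arrays were scaled to spike-ins. Adiponectin (Adipoq) had a log2 fold change of 0.16 ± 0.32 SE (0.33 with the slide as a block), and Pparg, the main regulator of adipocyte formation, −0.44 ± 0.18 SE (−0.18 with the slide as a block, 0.02 when arrays were scaled to spike-ins). Triglyceride synthesis (17 measured, shift −0.22, camera adjusted p = 0.228; 1 higher and 5 lower at an unadjusted p under 0.05), de novo lipogenesis (21; 0.07; 0.816; 2 and 4) and lipolysis (17; −0.08; 0.886; 0 and 1) did not pass. The shift of the triglyceride list ran from −0.35 to −0.14 without each array, that of lipogenesis from −0.08 to 0.31 and that of lipolysis from −0.07 to 0.06. Adjusted over the list alone, 1 lipogenesis gene was lower, and 0 genes of the lipolysis and triglyceride lists passed. Dgat2 and Gpam, enzymes of triglyceride synthesis, had log2 fold changes of −0.74 ± 0.20 and −0.61 ± 0.17 SE (−0.34 for Gpam with the slide as a block). Thrsp and Acacb, of fatty acid synthesis, had −0.94 ± 0.19 and −0.75 ± 0.20 SE. Hormone-sensitive lipase (Lipe) and its droplet partner Plin5 had −0.54 ± 0.18 and −0.39 ± 0.17 SE, where Lipe was −0.35 with the slide as a block and 0.03 with normexp background and quantile normalization, and Plin5 was 0.08 when arrays were scaled to spike-ins.

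Among stromal and vascular lists, extracellular matrix and fibrosis genes rose by 0.22 (26 measured, camera adjusted p = 4.91e-03, and adjusted p = 0.466 with an estimated correlation), and by 0.41 with the slide as a block. At an unadjusted p under 0.05, 6 were higher and 0 lower, with 0 over all genes and 4 higher adjusted over the list alone. Lysyl oxidase (Lox), which cross-links collagen, was 1.66-fold higher (log2 0.73 ± 0.17 SE) and the protease inhibitor Timp1 2.28-fold (log2 1.19 ± 0.29 SE), which were 0.27 and 0.17 with age as a covariate. The matrix call was lost without DIO replicate 1 (shift 0.13), with age as a covariate (−0.12, adjusted p = 0.93, the largest of its alternatives), without the filter on dim probes (0.12) and in fry. Endothelial markers rose by 0.27 (16 measured, camera adjusted p = 0.0219, and adjusted p = 0.421 with an estimated correlation), and by 0.41 with the slide as a block, with 2 higher and 0 lower at an unadjusted p under 0.05, 0 over all genes and 0 adjusted over the list alone. The junction proteins Cdh5 and Pecam1 had log2 fold changes of 0.54 ± 0.19 and 0.41 ± 0.15 SE, and the endothelial call was lost without DIO replicate 1 (shift 0.20), with age as a covariate (0.11), without the filter on dim probes (0.17), with the filter for signal on all arrays (0.20) and in fry. Adipocyte progenitor and stromal genes (20 measured, shift −0.01, camera adjusted p = 0.738, test direction up; 3 higher and 3 lower at an unadjusted p under 0.05) and lymphatic endothelial markers (8; 0.37; 0.141; 1 higher and 2 lower) did not pass. Adjusted over the list alone, 1 progenitor gene and 2 lymphatic genes were lower. The lymphatic list passed with the filter for signal on all arrays (0.46). Npnt and Pdgfrb of the progenitor list had log2 fold changes of −1.47 ± 0.28 and 0.57 ± 0.15 SE. Reln and Prox1 of the lymphatic list had −0.95 ± 0.24 and −0.82 ± 0.24 SE, each well above background on 1 of 3 DIO_CR_WR arrays.

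Cell cycle genes rose by 0.39 (21 measured, camera adjusted p = 4.12e-03, and adjusted p = 0.507 with an estimated correlation), and by 0.66 with the slide as a block, with 2 higher and 1 lower at an unadjusted p under 0.05, 0 over all genes and 0 adjusted over the list alone. The mitotic kinases Cdk1 and Aurka had log2 fold changes of 1.19 ± 0.31 and −0.53 ± 0.16 SE, with 2 of 3 Cdk1 probes in that direction and 0.74 for Cdk1 with the slide as a block. The call was lost without DIO replicate 1 (shift 0.29) and without DIO_CR_WR replicate 2 (0.18), and the shift was 0.64 without DIO replicate 3. It was also lost with age as a covariate (−0.05), without the filter on dim probes (0.34) and in fry. Unfolded protein response genes rose by 0.30 (17 measured, camera adjusted p = 0.0153, and adjusted p = 0.325 with an estimated correlation), and by 0.11 with the slide as a block, with 4 higher and 0 lower at an unadjusted p under 0.05, 0 over all genes and 0 adjusted over the list alone. Manf, a secreted factor of the stressed endoplasmic reticulum, had a log2 fold change of 0.70 ± 0.15 SE and Edem1, which clears misfolded proteins, 0.53 ± 0.17 SE. The shift was 0.18 without DIO replicate 1, and the call was lost without DIO_CR_WR replicate 3 (0.26), with age as a covariate (0.16), without the filter on dim probes (0.20) and in fry. Immediate early genes rose by 0.46 (20 measured, camera adjusted p = 4.91e-03, and adjusted p = 0.302 with an estimated correlation), and by 0.34 with the slide as a block. At an unadjusted p under 0.05, 5 were higher and 3 lower, with 0 over all genes, and adjusted over the list alone 2 were higher and 1 lower. Egr2 was 2.85-fold higher (log2 1.51 ± 0.33 SE). Egr3, which was not well above background on any DIO_CR_WR array, was at least 1.22-fold lower. The call of the immediate early list was lost without the filter on dim probes (shift 0.36) and in fry.

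Circadian clock genes fell by 0.30 (18 measured, camera adjusted p = 0.0387, and adjusted p = 0.325 with an estimated correlation), and had a shift of −0.59 with the slide as a block. Of its genes 8 were lower and 0 higher at an unadjusted p under 0.05, with 0 over all genes and 8 lower adjusted over the list alone. Fry gave the clock list the lowest adjusted p of the 35 lists (0.015). Ciart, a repressor of the clock, had a log2 fold change of −2.24 ± 0.30 SE and was well above background on 1 of 3 DIO_CR_WR arrays. Per3, not well above background on any DIO_CR_WR array, was at least 1.42-fold lower, and with Per3 at that bound the median log2 fold change of the list was −0.46 in place of −0.50. The other members lower at an unadjusted p under 0.05, chosen after their values were seen, included the clock output factors Dbp (−1.18 ± 0.26 SE), Hlf (−1.11 ± 0.21 SE) and Tef (−0.72 ± 0.14 SE). The camera call was lost without DIO replicate 1 (shift −0.18), with the filter for signal on all arrays (−0.22), with probe means (−0.17), with the replicate block (−0.30) and with age as a covariate, where the shift was 0.10 (adjusted p = 0.846, the largest of its alternatives). The shift was −0.56 without DIO replicate 3.

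The remaining lists did not pass in limma's camera. Cholesterol synthesis genes had a shift of 0.16 (24 measured, camera adjusted p = 0.13; 2 higher and 2 lower at an unadjusted p under 0.05), with −0.56 ± 0.16 SE for Fdft1, in which 1 of 2 probes went the other way. The cholesterol list passed with the slide as a block (shift 0.33, adjusted p = 0.00469; range over the alternatives 0.00411 to 0.924), and without DIO replicate 3 (0.35) or DIO_CR_WR replicate 3 (0.23). Insulin signalling genes had a shift of 0.14 (21; adjusted p = 0.41; 2 and 2), with 1.18 ± 0.33 SE for Pik3r1 (0.66 with the slide as a block) and −0.54 ± 0.16 SE for the glucose transporter Slc2a4. Antioxidant genes had a shift of 0.08 (18; adjusted p = 0.228; 2 and 1), with 0.81 ± 0.23 SE for Gsr and −1.05 ± 0.31 SE for catalase (Cat), which were 0.39 and −0.40 with the slide as a block. The antioxidant list passed with quantile normalization (0.30) and with normexp added (0.24). Epithelial and skin markers had a shift of −0.27 (13; adjusted p = 0.427; 1 and 4), and 0.08 with the slide as a block. Wfdc18 had a log2 fold change of 1.19 ± 0.19 SE and Cldn4, well above background on 1 of 3 DIO_CR_WR arrays, −1.04 ± 0.23 SE (−0.61 with the slide as a block). Haemoglobin and erythroid genes had a shift of 0.28 (6; adjusted p = 0.141; 0 and 0), with 0.39 ± 0.18 SE for Hbb-bs and −0.12 ± 0.28 SE for Slc4a1, which were 0.16 and −0.02 with the slide as a block, and Slc4a1 was 0.34 when arrays were scaled to spike-ins. The erythroid list passed with quantile normalization (0.44). Adjusted over the list alone, 1 epithelial gene was higher and 2 were lower, and 0 passed in the other lists of this paragraph. Without each array the shifts ran from 0.04 to 0.35 (cholesterol), 0.03 to 0.18 (insulin), 0.01 to 0.24 (antioxidant), −0.55 to −0.19 (epithelial) and 0.20 to 0.33 (haemoglobin).

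**Figure D2:**
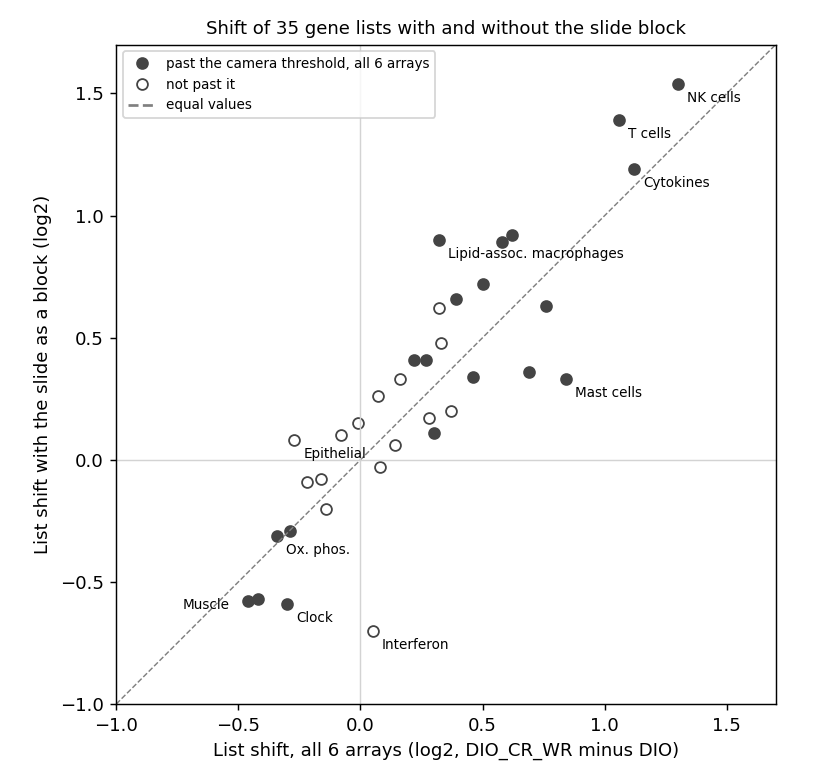
Shift of each of the 35 gene lists with all 6 arrays (x axis, log2) against the shift with the slide as a block (y axis, log2); filled circles are lists past the camera threshold with all 6 arrays, open circles the others, and the dashed line marks equal values. NK cell genes lie at 1.30 and 1.54, and interferon-stimulated genes at 0.05 and −0.70.

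Among single genes, those with the smallest p of each direction did not pass the test either, with an adjusted p of 0.108 in limma for all 24. The largest of the higher ones was Nfe2l3, a transcription factor of the NRF2 family, at 6.55-fold (log2 2.71 ± 0.32 SE). Several are genes of blood cells: the lymphocyte receptor Slamf6 was 4.80-fold higher (log2 2.26 ± 0.25 SE), Bst1, an ectoenzyme of bone marrow cells, 3.62-fold (log2 1.86 ± 0.19 SE), the NK receptor Klra9 2.94-fold (log2 1.55 ± 0.19 SE), Cd300ld 2.83-fold (log2 1.50 ± 0.18 SE) and the leukocyte tetraspanin Cd53 2.17-fold (log2 1.12 ± 0.14 SE). Spp1, on chromosome 5 with its probe at 104868502 to 104868561 of build mm9, went from −1.28 ± 0.08 in DIO to 0.29 ± 0.19 in DIO_CR_WR (log2 relative to the 75th percentile, SD, n = 3). Lhx8, Kctd10, Slc31a2 and Adamts15 had log2 fold changes of 1.44, 1.45, 1.24 and 1.71.

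Of the lower genes, Nmrk2 (Itgb1bp3 on the array), a kinase of NAD synthesis expressed mainly in muscle, had the largest difference, 18.0-fold (log2 −4.17 ± 0.40 SE). Its probe lies on chromosome 10 at 80662033 to 80662092 of build mm9, and its level went from 0.69 ± 0.79 in DIO to −3.48 ± 0.25 in DIO_CR_WR (log2 relative to the 75th percentile, SD, n = 3). Fgf6, a growth factor of muscle, had a log2 fold change of −1.91 ± 0.19 SE, and Ostn, a hormone of bone and muscle, −1.27 ± 0.17 SE. Tmem233 (−1.96), Mettl11b (−2.40), the neurotrophin Ntf5 (−1.58), the growth factor Gdf1 (−1.55), Cited4 (−1.41), Rasd2 (−1.31) and Hoxd10 (−1.17) followed. Gbx2, not well above background on any DIO_CR_WR array, was at least 1.59-fold lower. With the slide as a block the log2 fold changes of the 24 genes ran from −3.90 for Nmrk2 to 3.04 for Nfe2l3. Their direction could not turn in that model. The genes were chosen with no overlap between the groups, and DIO replicate 1 is the only DIO array on slide 1.

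Other named genes moved by more than 2 times under an alternative. Age as a covariate brought the log2 fold change of Ifng to 0.93, Msr1 to 0.46, H2-Oa to 0.11 and Ifih1 to −0.10, and those of S100a8 and Slc4a1 to 2.06 and −1.11. Quantile normalization brought Csf3r to −0.24, Siglech to −0.19, Cd36 to −0.26, Lipe to −0.19, Slc2a4 to −0.25, Ucp1 to −0.18, Pparg to −0.12 and Adipoq to 0.51. With normexp background added, Csf3r was −0.25, Siglech −0.13, Ciita −0.10, Cd36 −0.32, Plin5 −0.17, Acadvl −0.19, Uqcrc1 −0.23, Ndufb5 −0.34, Pfkm −0.38, Prox1 −0.36, Aurka −0.18, Pparg −0.11 and Adipoq 0.44. The mean of a gene's probes gave −0.26 for Cr2, −0.17 for Fdft1, 0.49 for Cdk1 and −0.31 for Cd4. Spike-in scaling raised all log2 fold changes, with a median of all genes of 0.27 in place of −0.20, so lower genes lay nearer 0, such as Cd36 at −0.20 and Uqcrc1 at −0.29.

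**Figure D3:**
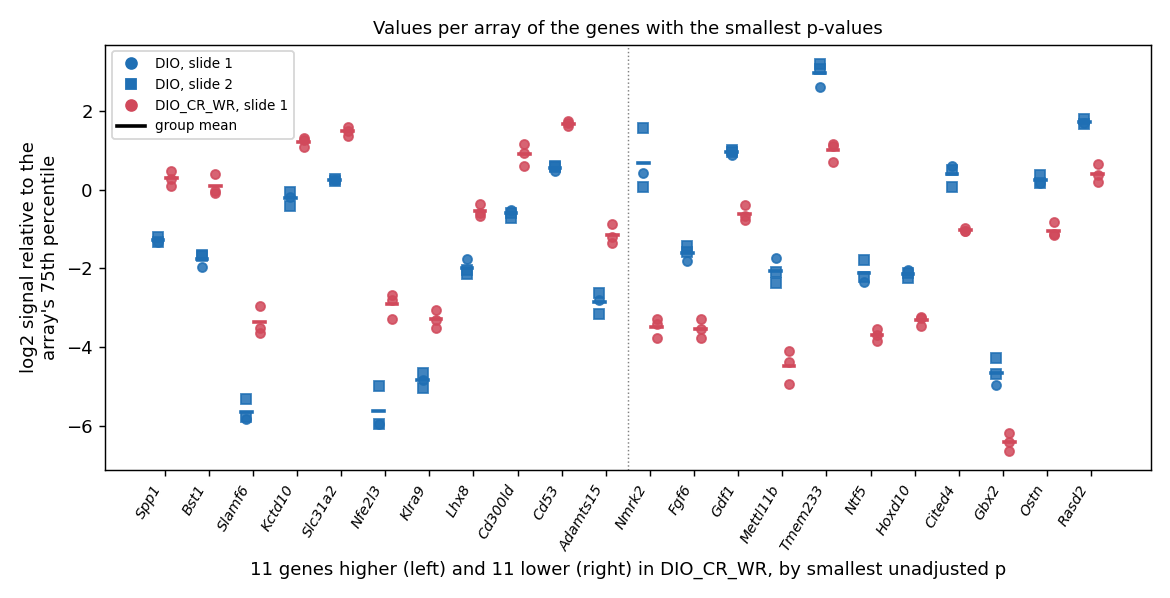
Level on each array (y axis, log2 signal relative to the array's 75th percentile) of 11 of the 12 genes higher and 11 of the 12 genes lower in DIO_CR_WR with the smallest unadjusted p; blue marks are DIO arrays (circles slide 1, squares slide 2), red circles are DIO_CR_WR arrays and lines are group means of 3 arrays. The mean of Nmrk2 is 0.69 in DIO and −3.48 in DIO_CR_WR, and that of Slamf6 is −5.63 and −3.37.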

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

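Slide 1 alone, the spike-in scaling, the common floor and the count at an unadjusted p under 0.05 were chosen after the data were seen, and the other settings were planned. Signal over background limits the dim genes, since fewer probes were well above background on the DIO_CR_WR arrays. The planned use of the deposited table of the whole series was not run, because the labels do not identify its columns. Unless stated, the cause of a difference was not tested.

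The count of genes past the threshold in limma, 0, stayed 0 with quantile normalization, median centring, no filter, every probe, probe means, the replicate block, age, the slide block, slide 1 alone, the common floor, an adjusted p under 0.1 and a 2-fold limit. It was 5 with normexp and quantile normalization, 63 with signal on all arrays, where fewer genes were tested, 26 with a trended, robust variance and 7 with spike-in scaling. Without each array it ran from 0 to 4057, the highest without DIO replicate 1 and 1 without DIO replicate 3. Leaving out DIO replicate 1 puts the groups on different slides, so counts without it cannot be told apart from a slide difference. At an unadjusted p under 0.05 the count of 7080 became 2761 with the slide block and 2759 on slide 1 alone, which compare fewer DIO arrays, and ran from 3204 to 9790 without each array, lowest without DIO replicate 2 and highest without DIO replicate 1. With the replicate block, though the numbers do not pair the arrays, the counts were 0 and 6168, with 20 lists. The 5660 lower and 1420 higher genes depend on the scaling: with spike-ins 4961 were higher and 907 lower, and the median of all genes went from −0.20 to 0.27.

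The 20 lists past camera were 12 without the filter, 9 with age, 0 with an estimated correlation and 11 with fry, and between 17 and 23 in the other settings. They ran from 14 without DIO replicate 1 to 24 without DIO replicate 3. Age as a covariate ended 12 of the 20 calls, among them macrophages, skeletal muscle and lymph node stroma, and the labelled ages do not overlap between the groups and rise by 1 month from sample to sample. The lists lost with spike-in scaling, at unchanged shifts, were B cells, neutrophils, lymph node stroma and glycolysis.

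Some values or test directions turned, of lists and genes not past the threshold except where stated. With normexp and quantile normalization the log2 fold change of Lipe was 0.03 and of Lep 0.23, and the shifts were −0.05 for interferon, 0.06 for adipocyte, 0.02 for lipolysis and 0.07 for fatty acid oxidation genes. Quantile normalization gave a log2 fold change of 0.27 for Lep, 0.04 for adipocyte and 0.06 for lipolysis genes. Without the filter the shifts were −0.05 for interferon, −0.11 for progenitor, −0.03 for lipogenesis and 0.04 for insulin genes, the last with the opposite direction in camera. With signal on all arrays interferon genes had −0.03 and lipogenesis genes 0.01, and with probe means lipogenesis genes had 0.07. Age gave log2 fold changes of 0.11 for Plin5, −0.01 for Adipoq and 2.35 for Ucp1, and shifts of −0.11 for MHC class II, 0.14 for adipocyte and −0.28 for lipogenesis genes. It also turned the called lists of lipid-associated macrophages to −0.25 and thermogenic genes to 0.22, and gave shifts of 0.10 for the clock, −0.12 for extracellular matrix and −0.05 for cell cycle genes, whose camera direction stayed. The slide block and slide 1 alone each gave log2 fold changes of 0.08 for Lep and 0.38 for Cd4, and shifts of −0.70 for interferon (called lower), 0.10 for lipolysis and 0.08 for epithelial genes. Fry, which does not compare with other genes, gave down for lists with shifts of 0.05 (interferon), −0.01 (progenitor), 0.07 (lipogenesis), 0.16 (cholesterol), 0.14 (insulin) and 0.08 (antioxidant). Spike-in scaling gave log2 fold changes of 0.13 for Ifih1, 0.08 for Plin5, 0.34 for Slc4a1, 0.45 for Lep, 0.37 for Cd4, 0.06 for Ucp1 and 0.02 for Pparg, with camera directions turned at unchanged shifts of 0.05 for interferon and −0.08 for lipolysis genes. Without each array the values ran from −0.31 to 0.15 for Slc4a1, −0.06 to 0.05 for Lep, −0.03 to 0.52 for Adipoq, −0.33 to 0.03 for Cd4, −1.09 to 0.17 for Ucp1, −0.24 to 0.44 for interferon, −0.09 to 0.10 for progenitor, −0.08 to 0.31 for lipogenesis and −0.07 to 0.06 for lipolysis genes.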

Other observations

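All tests of explanations described here, and the tests of gene families, were chosen after the results they concern were seen. Of 199 families of genes with a common symbol stem, 17 rose and 8 fell in limma's camera, 18 of the 25 held in the same direction with the slide as a block, 0 held with an estimated correlation, and 6 passed with fry. Klra genes, receptors of NK cells, rose by a shift of 1.34 (11 genes, 8 higher at an unadjusted p under 0.05, camera adjusted p = 1.5e-07, and adjusted p = 0.846 with an estimated correlation). Among the other rising families were Cxcl and Ccl chemokines (shifts 1.26 and 0.91), toll-like receptors (Tlr, 0.81), C-type lectins (Clec, 0.48) and matrix metalloproteinases (Mmp, 0.57). Major urinary protein genes (Mup), known as products of the liver, rose by 1.07, with 4 of 10 higher at an unadjusted p under 0.05, and clustered protocadherins (Pcdhb) by 0.62. The estimated correlation was 0.92 among Mup genes and 0.55 among Klra genes, so their members do not count as separate evidence. The rising families also include Rassf, Mcm, Mtmr, Dock, Snx and Zfp, and the immune families Gbp, Ifi, Irf and Traf did not pass (adjusted p = 0.365, 0.766, 0.73 and 0.17). Whether immune families as a set moved was not tested. The slide block brought Pcdhb to 0.24 (call lost on slide 1 alone) and Ccl to 0.55, and ended the calls of Mcm (0.41), Mtmr (0.19), Snx (0.25) and Zfp (−0.01). With an estimated correlation the adjusted p of Klra, Cxcl, Ccl, Tlr, Clec, Mmp and Pcdhb was 0.846 and that of Mup 0.889.

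Some families of mitochondria and ribosomes fell: cytochrome oxidase genes (Cox) by 0.26, complex I genes (Ndufb) by 0.28, mitochondrial ribosomal proteins (Mrps) by 0.14 and cytosolic ones (Rpl) by 0.20. The ribosomal families Rps and Mrpl and the mitochondrial Timm did not pass (adjusted p = 0.209, 0.179 and 0.154), but Mrpl passed with the slide as a block (shift −0.20) and on slide 1 alone, and Mrpl and Timm passed in fry. In fry the Mrps family had the lowest adjusted p of all families (0.00672), while camera with an estimated correlation gave 0.846 to 0.901 for the falling families named here. Fry does not compare with other genes, and all 6 families it passed were lower. They include Ddx and Ppp, whose shifts relative to all genes were 0 and 0.03, so a pass in fry does not set a family apart from all genes. Keratins (Krt, 37 genes) fell by 0.58 and odorant receptors (Olfr, 237 genes) by 0.49, but with the slide as a block their shifts were −0.23 and −0.05 and the calls were lost. Klra, Cxcl, Ccl, Tlr, Clec, Mmp, Mup and Pcdhb kept their direction and call with quantile normalization, with normexp and quantile normalization and with spike-in scaling. Of the other rising families named, Dock lost its call in all 3, Mtmr with normexp and with spike-ins, and Zfp in both quantile settings. Quantile normalization brought the shift of Cox to −0.15, Ndufb to −0.05, Mrps to −0.02 and Rpl to 0.03, all without a call, and Rpl turned upward. The calls of these 4 were also lost with normexp and quantile normalization, where Rpl had a shift of 0.06, and with spike-in scaling, at unchanged shifts. The Rpl median lay at percentile 24.3 of lists matched on brightness, so its fall is not told apart from that of genes as bright. By the same matching Ndufb lay at 5.26, Cox at 1.17 and Mrps at 2.74. The complex I family Ndufa, which also fell in camera (shift −0.16, adjusted p = 0.0241), lay at 31.6, so its fall is not told apart either. With quantile normalization Krt and Olfr kept a shift of −0.62 and −0.53 and their calls. The fall also depended on brightness across all genes. The median log2 fold change was −0.46 in genes under −4 (log2 relative to the 75th percentile), −0.02 between −2 and 0, and −0.29 above 2.

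The cytokine list and 4 lymphocyte lists (T, T helper, B and NK cells) were higher in DIO_CR_WR. In the model with the slide block their shifts ran from 0.89 (T helper) to 1.54 (NK cells). That model rests on DIO replicate 1 as the only DIO array on slide 1, so slide cannot be excluded. The medians of the 5 lists lay at percentile 100 (rounded) of random lists of matched brightness, which argues against brightness as the whole cause. More lymph node tissue in the sample may account for the lymphocyte lists, since the lymph node stroma list rose. Chst4 and Cr2, which nodes express, were lower, however. The B cell score minus the T cell score had a group difference of −0.08 (SE 0.25), too imprecise to decide whether they moved alike. On DIO_CR_WR replicates 1 to 3 the B cell score was 1.239, 0.093 and −0.109 and the T cell score 0.818, 0.203 and 0.326. On DIO replicates 1 to 3 the B cell score was −0.73, −0.651 and 0.157 and the T cell score −0.749, −0.654 and 0.056. A change in fat itself after weight regain stays open. So does age, if the labels give true ages. Neither was told apart from more lymph node tissue.

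The oxidative phosphorylation list was lower in DIO_CR_WR. With the slide as a block its camera adjusted p was 1.91e-05 (range over all alternatives 7.21e-06 to 0.392). That model rests on DIO replicate 1 as the only DIO array on slide 1, so slide cannot be excluded. Brightness cannot be excluded as a part either. The list lay at percentile 0.02 of brightness-matched lists, and at 0.05 after quantile normalization of the tested genes alone. Quantile normalization of all non-control spots, made before the filter, brought the shift from −0.34 to −0.12 and ended the call. The score difference of the list went from −0.31 (SE 0.05) to −0.05 (SE 0.03). Relative to all genes, the median log2 fold change of genes above 2 in brightness went from −0.09 to 0.07, a smaller move. With normexp as well it was 0.06 and the score difference −0.12 (SE 0.04), so the cause of the loss was not settled. Less skeletal muscle in the sample could account for the fall, since the muscle score moved by −0.46 (SE 0.2) beyond that of the list, as it would if muscle brought the difference. Within the groups, however, the list's score did not keep the order of the muscle score. On DIO replicates 1 to 3 the muscle score was 0.612, 0.494 and 0.045 and the list's score 0.182, 0.138 and 0.145. On DIO_CR_WR replicates 1 to 3 they were −0.242, −0.536 and −0.373, and −0.234, −0.153 and −0.077. A change in the adipocytes stays open and was not tested.

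The circadian clock list was lower in DIO_CR_WR. With the slide as a block its camera adjusted p was 4e-04 (range over all alternatives 4e-04 to 0.846). That model rests on DIO replicate 1 as the only DIO array on slide 1, so slide cannot be excluded. The clock score was 0.416 on DIO replicate 1, and 0.139 and 0.024 on DIO replicates 2 and 3. Without DIO replicate 1 the shift was −0.18 and the camera call was lost. Members with signal on all arrays had a shift of −0.22. Their median deviation per array, minus that of all genes with signal on all arrays, differed between the groups by −0.31 (SE 0.08). The camera call was lost in that setting too, but these values argue against dim probes as the whole cause of the fall. Another time of day at collection may account for it. Dbp, Tef, Hlf, Per1, Per2, Nr1d1 and Nr1d2, which peak together and were well above background on all arrays, had a mean log2 fold change of −0.69 (SE 0.07). Arntl, Npas2, Clock, Nfil3 and Cry1, which peak at the opposite time, had 0.28 (SE 0.23). These means are not relative to all genes, whose median was −0.20. Relative to all genes the first mean would lie nearer to no change and the second higher. The labels give no time of collection, so another time of day cannot be told apart from an effect of weight regain on the clock.

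Of the 10 ways to split the 6 arrays into 3 and 3, too few for a share under 0.05, 10 gave as many genes past the threshold as the real split, whose count was 0 (highest other 3). For genes at an unadjusted p under 0.05, 1 split, the real one, gave 7080 or more, and the highest other was 2539. For lists, 1 split gave 20 or more and the highest other was 18. For families, 1 split gave 25 or more and the highest other was 15.

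With each array placed between the means of the groups by genes chosen without it, from 0 at its own group to 1 at the other, DIO replicate 1 lay at 0.68 (median of 4000 genes), DIO replicates 2 and 3 at −0.19 and 0.16, and DIO_CR_WR replicates 1 to 3 at 0.04, 0.08 and 0.40. The genes for DIO replicate 1 were chosen between DIO arrays of slide 2 and DIO_CR_WR arrays of slide 1. Its position cannot be told apart from a slide difference.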
